A study of Mus musculus with 6 samples.

How the data were processed

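Total RNA was taken from 6 subcutaneous MTE-Ras tumours, 3 injected with PBS and 3 with PV-10, each from its own mouse. Per the labels' protocols the RNA was treated with DNase, 100 ng per tumour went into strand-specific libraries (NuGEN Universal RNA-Seq), and a NovaSeq 6000 gave pairs of 100-base reads. Per the labels' protocols the submitters found adapters with BBMerge 37.02, removed them with cutadapt 1.8.1, aligned reads to mm10 with STAR 2.7.7a and estimated gene values with RSEM 1.3.0 and Gencode release M21. Per the labels' protocols the authors tested genes with DESeq2 and gene ontology terms with clusterProfiler 4.6.2, and their results were not used here.

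The deposited count table holds whole-number gene counts that are not normalized, for 55450 genes and the 6 tumours. The deposited TPM table holds length-scaled transcript abundance from the same processing, scaled to the same total in each column. Table columns were matched to tumours through the library name in the labels. No row lacked a gene name, and 217 rows shared a symbol with another row. For a symbol with several rows the row with the highest mean count was used in gene lists, which applies to Ddit3. Total counts ran from 36730318 to 98717951 per tumour, so that 3 counts, the floor used for a gene at 0, corresponded to 0.0304 to 0.0817 CPM. RSEM shares reads among similar genes, so values of recent paralogs and pseudogenes are uncertain.

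The main test was edgeR's quasi-likelihood F test (edgeR 4.0.16, R 4.3.3, robust fit) on the deposited counts, with edgeR's expression filter at its defaults, TMM scaling and Benjamini-Hochberg adjustment over 22056 genes, calling genes at an adjusted p under 0.05. DESeq2, the tool the labels state, was run as an alternative. The biological coefficient of variation was 0.777. CPM values are TMM-scaled and given as mean ± SD over 3 tumours. Standard errors were taken as the size of the log2 change over the square root of the F statistic. The lowest adjusted p was 0.0443 and many genes share it, because the adjustment gives ranked genes a common value.

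In all, 35 gene lists for stress, cell death, immune response, cell types, tumour biology and RNA quality were fixed before the data were examined. They were tested with camera (limma 3.58.1, preset correlation 0.01, log2 CPM with a prior count of 2), two-sided, with adjustment over the 35 lists, and again with an estimated correlation and with fry. In the main comparison a list was called at a camera adjusted p under 0.05. Fry adjusted p are those of its directional test unless its mixed test, for changes in either direction, is named. The rule for named genes was also fixed beforehand. It takes the 10 largest rises and the 10 largest falls among called genes with an average log2 CPM of at least 1, groups that do not overlap and a symbol that is not a predicted gene's. From each list it takes up to 4 called members with the smallest adjusted p, or 2 abundant members where none was called. It always takes a short set of genes fixed with it, among them Hspa5, Ddit3, Atf4, Calr, Hmgb1, Epcam and Ptprc. Not all of the 90 genes it gives are printed. Ribosomal protein genes such as Rpl17, and Gm42418, were chosen after their values were seen.

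Library makeup was compared by exact two-sided permutation tests, for which the smallest p with 3 against 3 is 0.1. Transcript length and GC content were those of the longest transcript of each gene in Gencode release M21 on mm10, from which positions were also taken. The alternatives fixed beforehand were DESeq2 1.42.0, its size factors, library size alone, no low-count filter or a stricter one of 50 mean counts, a non-robust fit, limma-voom, limma on log2 TPM with a pseudocount of 1 or 0.1, removal of mitochondrially encoded genes, a replicate block, a log2 change of at least 1, and each tumour left out in turn. Added after seeing the data were removal of each library's length and GC trend (splines with 5 degrees of freedom), protein-coding genes alone, and PV-10 tumour 3 alone against PBS.

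The test was tried on simulated counts for the 22056 genes with the means, library sizes and spread of these tumours and 200 changed genes. Of genes changed by a log2 of 2, 66% were recovered with 12 unchanged genes called, and of genes changed by a log2 of 4, 83% with 14. With a length trend added, 125 unchanged genes were called, and 7 once it was removed. The added trend was equal in the 3 PV-10 libraries and used the length measure by which it was removed. The real libraries' slopes with length were taken against the mean of all libraries. In PV-10 tumours 1, 2 and 3 they were -0.298, -0.256 and -0.083 log2 CPM per doubling of length. In PBS tumours 1, 2 and 3 they were 0.133, 0.272 and 0.232, so PV-10 tumour 3 also lay below every PBS tumour. How well removal works in these tumours is thus not shown. A list shifted by a log2 of 2 was fitted at 2.03 with 0 other lists called. Simulated genes were drawn independently, so this cannot show how often camera's preset correlation gives false list calls when genes vary together. In these tumours the estimated correlation reached 0.759, for immediate early genes. Figures were drawn with matplotlib 3.10.9.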

Results

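RNA was sequenced from 6 tumours that grew under the skin of the flank of C57BL/6 mice after injection of MTE-Ras cells, a mouse tracheal epithelial cancer line transformed with oncogenic RAS. In 3 mice the tumour was injected with phosphate-buffered saline (PBS), and in the other 3 with PV-10, a formulation of the dye rose bengal that is injected directly into lesions. The labels give no dose and no time between injection and collection. Gene counts summed to 87386266, 92608727 and 98717951 in PBS tumours 1, 2 and 3, and to 60082066, 36730318 and 94203331 in PV-10 tumours 1, 2 and 3. Each tumour came from its own mouse, so the spread between tumours includes the spread between animals. The reads carried no molecular identifiers, so any floor taken from a count of 0 covers counting error only. The title of the series concerns immunogenic cell death, endoplasmic reticulum (ER) stress and apoptosis after PV-10, and the comparison of PV-10 with PBS tumours is the one the design allows.

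Of 22056 genes tested, 699 were higher and 423 lower in PV-10 than in PBS tumours (edgeR quasi-likelihood test, adjusted p under 0.05, n = 3 per group). In each called gene, chosen by this test, the 3 PV-10 tumours lay on one side of the 3 PBS tumours. Plec, the cytolinker plectin (ENSMUSG00000022565.15, mm10 chromosome 15, 76170974 to 76232574), fell from 2973 ± 58.1 to 528 ± 238 CPM (counts scaled to library size, mean ± SD, n = 3 each), a log2 change of -2.49 (SE 0.37, edgeR adjusted p = 0.0443). Dst, the related cytolinker dystonin, fell from 613 ± 93.7 to 134 ± 34.9 CPM (log2 change -2.20). Kmt2d, a histone H3 lysine methyltransferase, fell from 683 ± 8.98 to 137 ± 61.8 CPM (log2 change -2.32). The other named falls were Tenm4 (-2.85), Nectin1, an adhesion molecule (-2.37), Disp2 (-2.30), Adgra2 (-2.25), Slc6a9, a glycine transporter (-2.22), and Hivep3 (-2.18), all as log2 changes. With the trend of each library with transcript length and GC content removed, the log2 changes of Plec, Dst and Kmt2d became -0.94, -1.33 and -0.92, and those of Tenm4, Nectin1, Disp2, Adgra2, Slc6a9 and Hivep3 -1.79, -1.41, -1.44, -1.06, -1.80 and -1.08, none of them called. AC129217.1 fell from 9.005 ± 6.75 to 0.180 ± 0.189 CPM and had 0 counts in PV-10 tumour 1.

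The largest rises were mostly in genes with few or no counts in PBS tumours. Tnmd, which encodes tenomodulin (ENSMUSG00000031250.8, mm10 chromosome X, 133850980 to 133865577), had 0 counts in all 3 PBS tumours and 16.6, 2.46 and 0.194 CPM in PV-10 tumours 1, 2 and 3. Its mean in PV-10 tumours was 198-fold above a floor of 3 counts per library. That floor takes each read as a separate molecule, so 198-fold is not a lower bound if several reads were counted per molecule. Duxf3 (log2 change 5.30), the lincRNA AC140207.2 (4.81), Faim2 (4.70), Wscd2 (4.70), Gprin2 (4.44) and the vomeronasal receptor gene Vmn2r53 (4.43) also rose, as log2 changes. More abundant were the histone H2A gene Hist1h2ao, at 2.28 ± 1.10 against 70.8 ± 95.5 CPM, and Rps12l1, a processed pseudogene of a ribosomal protein gene, at 4.84 ± 3.10 against 63.0 ± 47.7 CPM. Duxf3, Hist1h2ao and Rps12l1 have near-identical copies elsewhere, so reads could be split among the copies. In all 10 genes with the largest rises PV-10 tumour 3 had a lower level than PV-10 tumours 1 and 2.

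PV-10 tumour 3 lay nearer to the PBS tumours than to the other PV-10 tumours: its log2 CPM correlated at 0.909, 0.919 and 0.930 with PBS tumours 1, 2 and 3 and at 0.874 and 0.822 with PV-10 tumours 1 and 2. On the first principal component, with 57.1% of the variance, it lay at -46, the PBS tumours between -153.4 and -92.8, and PV-10 tumours 1 and 2 at 182.4 and 224.4. Both the number and the split of called genes moved with the libraries and the scale. Without PBS tumour 1, 2 or 3, edgeR called 1, 2 and 1 genes, without PV-10 tumour 1 or 2 it called 2 and 5, and without PV-10 tumour 3 it called 11399. Genes at an unadjusted p under 0.05 numbered 6851, 6378, 6039, 4804, 4614 and 13560 in these settings, against 6627 with all tumours. The number of genes tested also changed, from 22056 to between 22750 and 28118. With all tumours the lowest adjusted p, 0.0443, lay close to the threshold, so the count of called genes can change sharply. Scaling by library size alone gave 980 higher and 1461 lower genes, and limma on log2(TPM + 1) gave 162 higher and 2755 lower, while the median log2 change over all tested genes was 0.30 with TMM, 0.21 with library size and -0.21 with TPM.

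Members of the ER stress list changed unevenly. Of 27 genes for ER chaperones and ER-associated degradation, 4 rose, 0 fell and 23 did not pass the test, and adjusted over the list alone 4 were higher and 4 lower. Dnajb9, an ER co-chaperone (ENSMUSG00000014905.4, mm10 chromosome 12, 44205559 to 44210326), rose from 84.0 ± 12.8 to 224 ± 52.8 CPM, a log2 change of 1.41 (SE 0.29, edgeR adjusted p = 0.0443). Sec61b, a subunit of the ER translocon, rose from 27.1 ± 3.01 to 93.0 ± 45.6 CPM, and Manf, a secreted protein induced by ER stress, from 112 ± 6.60 to 255 ± 66.6 CPM. Selenos, which takes part in ER-associated degradation, rose from 34.2 ± 3.96 to 70.9 ± 10.6 CPM. With the length and GC trend removed, the log2 changes of Dnajb9, Sec61b, Manf and Selenos went from 1.41, 1.78, 1.19 and 1.05 to 0.59, 0.78, 1.01 and -0.042, none of them called. The major ER chaperone Hspa5 (BiP) was at 349 ± 6.76 CPM in PBS and 301 ± 42.3 CPM in PV-10 tumours and did not pass the test (edgeR adjusted p = 0.592). The list as a whole had a median log2 change of -0.17 and was not called (camera adjusted p = 0.431).

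Genes of the PERK-ATF4-CHOP branch of the integrated stress response were lower as a group. Of 24 tested members 0 were called singly, over all genes or adjusted over the list alone, but 21 had a negative log2 change, with a median of -0.70 (camera adjusted p = 0.000635). The adjusted p was 0.943 with an estimated correlation between genes. That setting gave 0.943 or 0.948 for each of the 35 lists, so it does not tell called lists from others. Fry, which does not compare the list with other genes, gave an adjusted p of 0.253. The transcription factor genes Atf4 and Ddit3 (CHOP) were at 234 ± 23.8 and 31.0 ± 8.31 CPM in PBS tumours and at 218 ± 31.7 and 22.1 ± 8.80 CPM in PV-10 tumours, and neither passed the test. Against PBS, PV-10 tumour 3 alone gave a median of -0.23 for this list (camera adjusted p = 0.0752).

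Among 36 genes of the apoptosis machinery 2 rose, both of them paralogs of the anti-apoptotic BCL2 family member A1. Bcl2a1b rose from 8.04 ± 1.07 to 29.3 ± 10.97 CPM and Bcl2a1d from 2.37 ± 0.669 to 8.74 ± 4.65 CPM, and because the paralogs are nearly identical their reads could be shared. With the length and GC trend removed, their log2 changes went from 1.86 to 0.11 and from 1.88 to 0.23. The list's median log2 change was 0.17 (camera adjusted p = 0.941), and adjusted over the list alone 5 members were higher and 2 lower.

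Of 27 tested genes for immunogenic cell death signals and their receptors, 1 fell and 0 rose, and adjusted over the list alone 0 were higher and 2 lower. That gene was Lrp1, a receptor that binds calreticulin (ENSMUSG00000040249.15, mm10 chromosome 10, 127538161 to 127621148), which fell from 3019 ± 448 to 734 ± 249 CPM, a log2 change of -2.04 (SE 0.33, edgeR adjusted p = 0.0443), which became -0.63 (adjusted p = 0.173) with the length and GC trend removed. The calreticulin gene Calr was at 550 ± 2.65 CPM in PBS and 737 ± 95.2 CPM in PV-10 tumours, and Hmgb1 at 375 ± 84.4 and 558 ± 131 CPM. Neither passed the test (edgeR adjusted p = 0.298 and 0.240), although all 3 PV-10 tumours lay above all 3 PBS tumours for Calr. The list's median log2 change was -0.20 (camera adjusted p = 0.281). Exposure or release of the proteins, by which these signals act, is not measured by RNA.

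**Figure D1:**
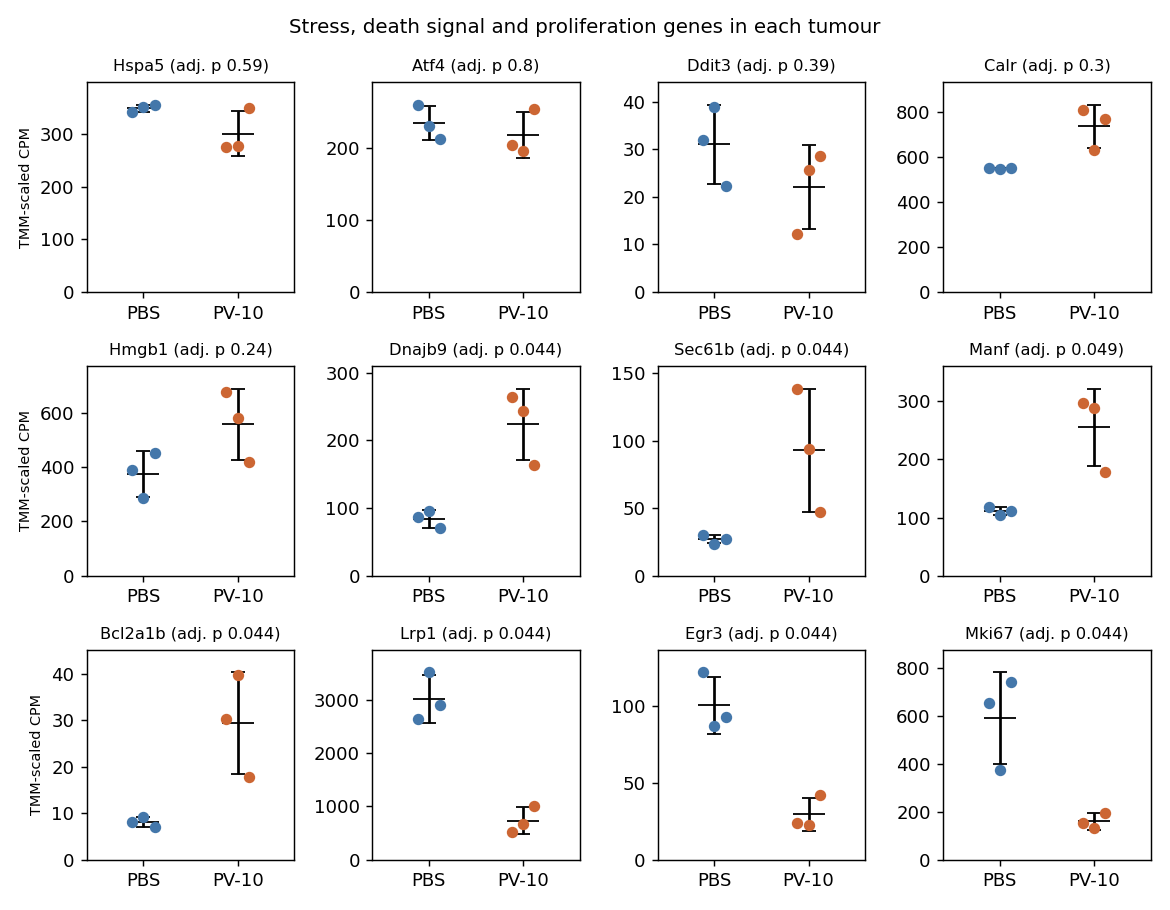
CPM after TMM scaling (vertical axes, starting at 0) of 12 genes in the 3 PBS tumours (blue) and the 3 PV-10 tumours (orange), where each point is a tumour, the wide bar is the mean and the error bar the SD, with the edgeR adjusted p above each panel. Dnajb9, Sec61b, Manf and Bcl2a1b were higher and Lrp1, Egr3 and Mki67 lower in PV-10 tumours, while Hspa5, Atf4, Ddit3, Calr and Hmgb1 did not pass the test.

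Immediate early genes, which respond within minutes to growth signals and to tissue handling and mostly encode transcription factors, were lower as a group. Of 20 members 19 had a negative log2 change, with a median of -0.87 (camera adjusted p = 8.12e-05, but adjusted p = 0.943 with an estimated correlation). Singly, 1 fell: Egr3, from 100 ± 18.6 to 29.5 ± 10.7 CPM. The matrix remodelling and wound repair list was lower (median -0.42, camera adjusted p = 0.033, but adjusted p = 0.943 with an estimated correlation), with 2 of 23 members falling. These were Tnc, the matrix protein tenascin C, from 1272 ± 580.9 to 410 ± 31.7 CPM, and Itga5, the fibronectin receptor subunit, from 348 ± 38.7 to 118 ± 55.5 CPM. Once the length and GC trend was removed, Tnc and Itga5 went from -1.63 to -0.76 and from -1.56 to -0.84 on the log2 scale, neither of them called. Hypoxia and glycolysis genes were lower (median -0.55 over 24 genes, camera adjusted p = 0.033) and so were endothelial markers (median -0.71 over 20 genes, camera adjusted p = 0.0482), with no member of either list called. For both the adjusted p was 0.943 with an estimated correlation, a value that lists not called also had. The hypoxia and matrix calls were also lost with the stricter low-count filter, with protein-coding genes alone and without PV-10 tumour 1. The endothelial call was lost with library size, limma-voom, TPM, the stricter filter, protein-coding genes alone, and without PV-10 tumour 1 or 2, and its median went to -0.24 (adjusted p = 0.398) with the length and GC trend removed.

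Nuclear-encoded genes of oxidative phosphorylation were higher, with a median of 0.84 (camera adjusted p = 0.0482), 7 of 27 members rising and 0 falling. The adjusted p was 0.943 with an estimated correlation, and the median went to 5e-04 (adjusted p = 0.966) with the length and GC trend removed. The call was also lost with library size, limma-voom, TPM, no low-count filter, and each tumour left out. Among them, Ndufb9 of complex I rose from 55.1 ± 11.6 to 227 ± 108 CPM, Cox7a2 and Cox4i1 of complex IV by 2.11 and 1.32 on the log2 scale, and Atp5h of the ATP synthase by 1.78. With the trend removed, the log2 changes of Ndufb9, Cox7a2, Cox4i1 and Atp5h were 0.97, 0.70, 0.52 and 0.29, none of them called. Differentiated skin and hair follicle markers were higher (median 2.06 over 14 tested genes, camera adjusted p = 0.033), with 0 members called and 13 of 14 under 10 CPM in PV-10 tumours, and the adjusted p was 0.943 with an estimated correlation. For 4 of its 12 positive members the level expected from genome-wide background was at least 50% of the rise. The summed level of the list was 214, 105 and 99.6 CPM in the PBS tumours and 75.6, 93.3 and 129 CPM in the PV-10 tumours. Its call was lost with no filter or the stricter one, and on leaving out any tumour but PBS tumour 1. Adjusted over the list alone, 14 oxidative phosphorylation genes were higher and 1 lower, 4 matrix genes lower, 1 immediate early gene lower and 1 skin gene higher. Fry's directional test called none of the immediate early, matrix, hypoxia, endothelial, oxidative phosphorylation and skin lists (fry adjusted p = 0.2655, 0.449, 0.575, 0.680, 0.163 and 0.163). Its mixed test, for changes in either direction, gave an adjusted p of 0.0431 for oxidative phosphorylation and 0.0273 for skin. For the immediate early, matrix, hypoxia and endothelial lists the mixed test gave 0.0731, 0.0665, 0.109 and 0.331.

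PV-10 tumour 3 alone against PBS ended all 7 list calls, with medians of -0.23 for the integrated stress response, -0.18 for immediate early genes, -0.09 for matrix, -0.03 for hypoxia, 0.03 for endothelial markers, 0.50 for oxidative phosphorylation and 0.33 for skin. Of the 7 lists, 5 stayed called with the length and GC trend removed: immediate early genes at -0.87 (camera adjusted p = 1.35e-04), the integrated stress response at -0.54 (0.0019), skin at 2.04 (0.0122), matrix at -0.74 (0.014) and hypoxia at -0.49 (0.0197). These calls used the preset correlation, and an estimated one was not tried with the trend removed. The trend was that of the longest transcript, whose log2 length correlated with log2 changes at -0.434. Effective length, taken from counts over TPM, correlated at -0.528, so part of a length trend may remain.

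Proliferation genes fell in 2 of 30 cases: Mki67, the marker of cycling cells, from 591 ± 192 to 160 ± 33.8 CPM, and Cenpf, a kinetochore protein gene, from 73.1 ± 26.2 to 21.5 ± 5.26 CPM. With the trend removed they went from -1.89 to -1.25 and from -1.76 to -1.36 on the log2 scale, neither of them called. The cell cycle list itself was not called (median -0.33, camera adjusted p = 0.172). In the epithelial tumour cell list (median 0.31) 1 of 24 tested genes fell. Epcam was at 0.233 ± 0.202 CPM in PBS and 0.801 ± 0.588 CPM in PV-10 tumours (edgeR adjusted p = 0.535), with 0 counts in PBS tumour 1. Among 23 genes of the NRF2 and oxidative stress response (median -0.08) the peroxiredoxin gene Prdx1 alone rose, from 90.3 ± 13.8 to 308 ± 134 CPM. Of 16 cytosolic heat shock genes (median -0.13) the mitochondrial co-chaperonin gene Hspe1 alone rose, from 64.1 ± 9.59 to 304 ± 145 CPM. With the length and GC trend removed, the log2 changes of Prdx1 and Hspe1 went from 1.77 to 0.95 and from 2.24 to 0.68, neither of them called.

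Immune lists were not called in the comparison of all 6 tumours, and each held at most 1 gene that changed. The leukocyte gene Ptprc (CD45) was at 66.1 ± 5.76 CPM in PBS and 75.6 ± 13.7 CPM in PV-10 tumours (edgeR adjusted p = 0.638). The chemokine gene Ccl7 rose from 11.04 ± 0.768 to 40.6 ± 20.2 CPM, the costimulatory ligand gene Cd86 from 14.5 ± 2.94 to 37.7 ± 8.90 CPM, and the proteasome activator gene Psme2 from 15.97 ± 4.13 to 37.3 ± 5.51 CPM. Klrd1 (CD94), an NK cell receptor gene, rose from 2.30 ± 0.0968 to 10.5 ± 3.73 CPM, and Themis, a T cell signalling gene, from 0.339 ± 0.184 to 4.28 ± 1.58 CPM. With the length and GC trend removed none of these 5 was called, and the log2 changes of Ccl7, Cd86, Psme2, Klrd1 and Themis went from 1.88, 1.37, 1.22, 2.19 and 3.65 to -0.001, 0.77, 0.24, 0.38 and 3.33. Median log2 changes were 1.02 for T cell markers, 0.80 for cytotoxic and NK cell markers, 1.31 for B and plasma cell markers, 1.03 for neutrophil markers, 0.32 for dendritic cell markers, -0.09 for macrophage and monocyte markers and 0.15 for mast cell and eosinophil markers. The level expected from genome-wide background was at least 50% of the rise for 8 of 14 positive B and plasma cell markers and 5 of 19 positive T cell markers, and the NK cell median went to -0.19 with the length and GC trend removed. Medians were -0.14 for the type I interferon response, -0.0091 for the interferon gamma response, 0.14 and 0.26 for MHC class I and class II antigen presentation, 0.33 for cytokines and chemokines and 0.26 for immune checkpoints. Without PV-10 tumour 3 the interferon gamma, type I interferon and MHC class I lists were called lower, with medians of -0.76, -0.49 and -0.33 (camera adjusted p = 0.00191, 0.00191 and 0.0185). Camera compares a list with all other genes, and the median over all tested genes was 0.89 in that setting against 0.30 in the main comparison. An estimated correlation was tried only in the main comparison, where it was 0.627, 0.573 and 0.494 for these lists (camera adjusted p = 0.943 for each). T cell markers were called higher with the stricter low-count filter, with TPM and a pseudocount of 1 and without PV-10 tumour 1 (camera adjusted p = 0.0452, 0.0179 and 0.0250), and NK cell markers without PV-10 tumour 1 (0.0253).

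Of the remaining lists, none of which was called and none of which held a called gene, p53 targets had a median of -0.19, pyroptosis and necroptosis genes 0.37, fibroblast and pericyte markers 0.22, skeletal muscle markers 1.95, adipocyte markers 1.599, red blood cell markers 1.13, nerve and Schwann cell markers 0.26 and mitochondrially encoded transcripts -0.19. Adjusted over the list alone, members higher and lower were 5 and 0 for NRF2, 3 and 3 for p53, 5 and 3 for fibroblasts, 2 and 4 for epithelial markers, 1 and 2 for the cell cycle, and 2 and 0 each for MHC class I and for cytokines. The heat shock, MHC class II, T cell and NK cell lists each had 1 higher on that basis, and the other uncalled lists not yet given had 0. Camera adjusted p over the 28 lists not called ran from 0.168 to 0.941. Camera, which compares a list with all other genes, placed the apoptosis, MHC class I, immune checkpoint, dendritic cell and nerve lists on the lower side although their medians were positive. Median and mean differed in sign for the NRF2, interferon gamma and macrophage lists.

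**Figure D2:**
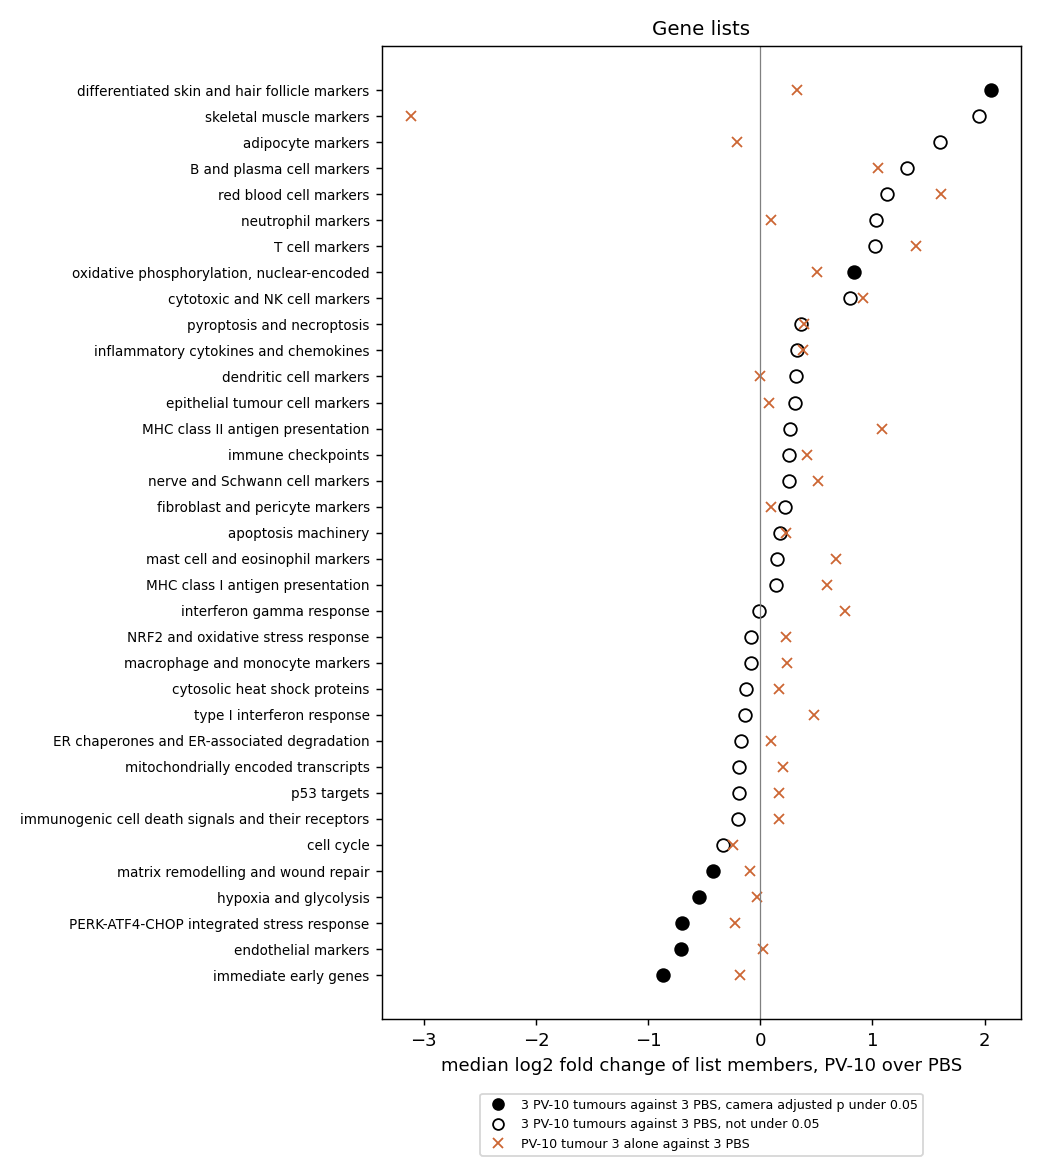
Median log2 fold change of the tested members of 35 gene lists fixed before the data were examined (horizontal axis, PV-10 over PBS), with circles for the 3 PV-10 against the 3 PBS tumours, filled where the camera adjusted p was under 0.05, and crosses for PV-10 tumour 3 alone against the 3 PBS tumours. The 7 filled circles run from -0.87 for immediate early genes to 2.06 for skin and hair follicle markers, and the crosses of these lists lie nearer to 0.

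The makeup of the libraries also differed between the groups. Cytosolic ribosomal protein genes, a group chosen after the data were seen, took 3.27 ± 0.390% of counts in PBS and 8.41 ± 2.42% in PV-10 tumours (exact two-sided permutation p = 0.1, the smallest possible with 3 against 3), and 50 of 82 rose while 0 fell. Their median log2 change was 1.34, and 0.47 with the length and GC trend removed. Rpl17 rose from 512 ± 36.7 to 2764 ± 1260 CPM. The 10 most abundant genes took 13.5 ± 0.222% against 25.8 ± 1.83% of counts, and protein-coding genes 88.1 ± 0.936% against 73.3 ± 3.09% (exact permutation p = 0.1 for each). Gm42418, which overlaps a ribosomal RNA repeat, took 3.05 ± 0.475% against 10.6 ± 1.40% of counts. Transcript length went with the direction of change: over 12898 genes with an average log2 CPM of at least 1, the median log2 change was 1.34 for transcripts of up to 500 bases, 0.33 between 1000 and 2000 bases and -0.89 above 8000 bases. The genes called higher had a median transcript length of 1596 bases and those called lower of 7480 bases. With the trend of each library with transcript length and GC content removed, an alternative chosen after seeing the data, edgeR called 0 genes (5198 at an unadjusted p under 0.05, and no other tool was run on it).

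**Figure D3:**
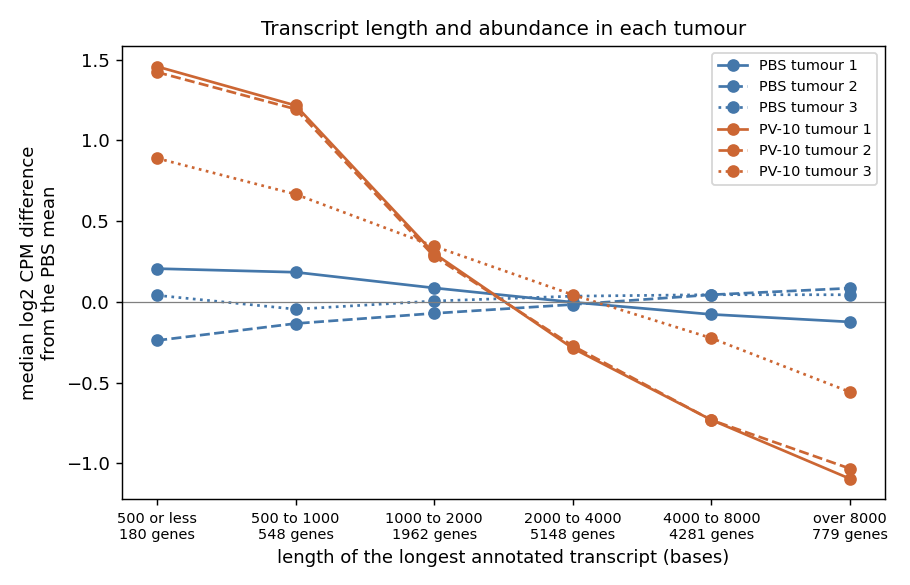
Median difference in log2(CPM + 0.5) from the mean of the PBS tumours (vertical axis) for genes in 6 classes of transcript length in bases (horizontal axis, with the number of genes), with a line for each tumour. In the shortest class PV-10 tumours 1, 2 and 3 lie at 1.46, 1.42 and 0.89, and in the longest at -1.10, -1.03 and -0.56.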

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

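All tests in this part were chosen after the result was seen. Beyond leaving out each tumour in turn, no rule for single outlying tumours was applied, as groups of 3 are too small for one. Receptor genes of sensory neurons, which no comparison above uses as a group, had counts in PV-10 tumours 1 and 2 above the level in the PBS tumours. Over 1407 olfactory receptor genes, of which 269 passed the filter for testing, the level was 0.209 CPM per kilobase in PV-10 tumour 1 and 0.213 in PV-10 tumour 2, against at most 0.0102 in the PBS tumours and 0.0150 in PV-10 tumour 3. In PV-10 tumours 1 and 2, 84.2% and 56.4% of these genes had a count, and in PBS tumours 1, 2 and 3, 8.5%, 18.1% and 12.6%.

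Deeper sequencing is argued against, since the larger total of PV-10 tumours 1 and 2 was 0.688 times the smallest PBS total. A candidate explanation is background from the whole genome, such as residual DNA despite the DNase step. In line with it, the unrelated vomeronasal receptor genes reached 0.201 and 0.231 CPM per kilobase in the same tumours, at most 1.085 times apart from the olfactory receptor genes, and counts rose with transcript length (Spearman's rho across genes 0.739 and 0.557, genes not being independent replicates). Such background is argued against as the source of most genes called higher: for 3.1% of them (22 of 699) the level expected from it was at least 50% of the rise, among them Vmn2r53. In all 699 PV-10 tumour 3 lay above every PBS tumour, so genes raised in PV-10 tumours 1 and 2 alone were not among them. The 6884 genes called higher without PV-10 tumour 3 were not examined for background. How PV-10 treatment, tissue damage or RNA yield relates to this background was not tested.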

How the results depend on the processing

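The alternatives of length and GC trend removal, protein-coding genes alone and PV-10 tumour 3 alone were chosen after seeing the data, as was the count over splits. The 1122 called genes (699 higher, 423 lower) became 2537 (1469, 1068) with DESeq2 size factors, 2441 (980, 1461) with library size alone, 4664 (2037, 2627) with no low-count filter, 2705 (1593, 1112) with a stricter one, 5720 (3471, 2249) with DESeq2, 2097 (866, 1231) with limma-voom, 2917 (162, 2755) and 3175 (342, 2833) with limma on TPM with a pseudocount of 1 and 0.1, and 2805 (1549, 1256) with protein-coding genes alone. They became 18 (15, 3) with PV-10 tumour 3 alone, of which 10 were among the 1122, and 0 (0, 0) with the length and GC trend removed, and the cause was not tested. The non-robust fit (1483), removal of mitochondrially encoded genes (1142) and a log2 change of at least 1 (1122) stayed within 1.5 times. Leaving out one tumour gave 1 to 11399 called genes, 1 to 6884 higher and 0 to 4515 lower, the highest each time without PV-10 tumour 3. Leaving one out also leaves fewer samples and changes the number of genes tested. All 1122 were called, in the same direction, with DESeq2, with its size factors and without PV-10 tumour 3.

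The labels do not tie equally numbered tumours together. Deviations from the group mean of equally numbered tumours 1, 2 and 3 correlated at -0.049, 0.071 and 0.072. PV-10 tumour 1 correlated best with PBS tumour 2 (0.08), but PV-10 tumours 2 and 3 correlated best with the PBS tumours of the same number. With 3 tumours per group, correlations this small cannot decide whether the tumours are paired. A replicate block gave 2872 called genes (1054, 1818) and ended the oxidative phosphorylation call. Of the 10 splits of the 6 tumours into 3 and 3, 1, the real one, gave as many as 1122 called genes and the highest other gave 0, but 10 splits are too few for a share under 0.05.

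The call of the integrated stress response list was lost with an estimated correlation and with fry, which change the p (0.943 and 0.253) and not the median of -0.70, and with PV-10 tumour 3 alone, at -0.23. With a tumour left out it stayed called, over a range of -1.02 to -0.42. ER chaperones were called lower with no filter (-0.28) and without PV-10 tumour 3, over a range of -0.22 to -0.0464 with a tumour left out. Immunogenic cell death genes were called lower with no filter (-0.26), with TPM and a pseudocount of 1 (-0.85) and without PBS tumour 3 or PV-10 tumour 3, over a range of -0.45 to -0.0033. The apoptosis list was never called by camera or by fry's directional test. Fry's mixed test, for changes in either direction, gave an adjusted p of 0.0431 for it and 0.0471 for ER chaperones. For the integrated stress response it gave 0.0582, and for immunogenic cell death genes 0.05075. Among the other uncalled lists it was under 0.05 for the p53, pyroptosis, T cell, NK cell, B cell, macrophage, epithelial and nerve lists. With PV-10 tumour 3 alone, medians turned positive for the interferon gamma response (0.75) and endothelial markers (0.026), and camera's direction, though not the median's sign, turned for MHC class I (0.60). Lists not called in the main comparison were also called lower in some settings without a low-count filter, with TPM or with a tumour left out: heat shock, p53, type I interferon, interferon gamma, macrophage, cell cycle and mitochondrially encoded genes. The median log2 change over all tested genes was 1.63 with no filter and 0.89 without PV-10 tumour 3, against 0.30 in the main comparison. Calls lower in these settings, also of ER chaperones and immunogenic cell death genes, can thus partly reflect the genes that camera compares with. Skeletal muscle markers were called higher with TPM. With the length and GC trend removed, oxidative phosphorylation went to 5e-04, Selenos to -0.042 and Ccl7 to -0.001, and mitochondrially encoded transcripts were called lower (-1.63, camera adjusted p = 3.12e-05). Direction also changed, with neither value called, in 81 cases over the lists and 88 over the named genes. The cause of these changes was not tested.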

Other observations

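Genes induced by interferon gamma varied among the PV-10 tumours. Cxcl9, a chemokine gene induced by interferon gamma, was at 143, 34.5 and 64.0 CPM in the PBS tumours and at 15.5, 54.8 and 204 CPM in PV-10 tumours 1, 2 and 3, and the GTPase gene Iigp1 at 95.5, 50.8 and 113 against 52.3, 182 and 295 CPM. Against PBS, PV-10 tumour 3 alone had a median log2 change of 0.75 over the interferon gamma list, 1.09 over MHC class II, 0.60 over MHC class I and 1.39 over T cell markers. With PV-10 tumours 1 and 2 alone the medians were -0.76 for interferon gamma (camera adjusted p = 0.00191) and -0.33 for MHC class I (0.0185). Those for MHC class II and T cell markers, not called, were -0.22 and 0.72. These calls used the preset correlation, and an estimated one was not tried with these tumours alone. The values of PV-10 tumour 3 describe 1 tumour, with no spread of its own, and PV-10 tumour 3 was not tested against PV-10 tumours 1 and 2.

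Skeletal muscle genes were present in some tumours. Summed over the list they reached 144, 29.8 and 17.1 CPM in PBS tumours 1, 2 and 3, and 212, 748 and 14.3 CPM in PV-10 tumours 1, 2 and 3. The fast myosin gene Myh4 was at 19.0 and 110 CPM in PV-10 tumours 1 and 2 and at 0 in PV-10 tumour 3. Mast cell genes varied within both groups: the protease gene Mcpt1 was at 0.557, 122 and 0.656 CPM in the PBS tumours and 1.19, 7.23 and 62.7 CPM in the PV-10 tumours. Mdm2, the p53 regulator, was at 1634 ± 263 CPM in PBS and 1725 ± 244 CPM in PV-10 tumours.

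All tests below were chosen after the result was seen. Short transcripts were higher and long ones lower in PV-10 tumours, and length and GC content together accounted for 34.7% of the variance of log2 changes across 12898 genes. With the trend removed, 0% of the called genes stayed called: their median absolute log2 change went from 1.69 to 0.87 (interquartile range 0.54 to 1.28) and the lowest adjusted p from 0.0443 to 0.0738. Since 0.87 still exceeded the median of 0.70 over all tested genes, while these genes had been picked for large changes, it stays open whether the trend is the whole cause. Ribosomal protein genes had a higher median than 98.03% of 10000 random lists matched on effective length, GC content and expression, and than 100% of those matched on the longest transcript, but the matched genes were longer (log2 relative effective length -1.77 against -2.04), so this decides nothing. Length slopes of the groups did not overlap, with a gap of 0.216 log2 CPM per doubling of length, so an effect of PV-10 on the tumour and a difference in RNA or library quality between the groups cannot be told apart.

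Low counts were scarce beside higher ones in some libraries: in PV-10 tumour 2, 833 genes had 6 to 10 counts and 1597 had 21 to 25, while in PBS tumour 3 the same classes held 1737 and 542 genes. A minimum count applied to the table is argued against, since each library had at least 895 genes with 1 to 5 counts. A candidate explanation is that several reads were counted per original molecule, as duplicate copies would give, since the share of olfactory receptor genes at 0 gave at least 9.52 reads per detected molecule in each library. Unequal true levels among these genes would raise that estimate too, which was not tested, and no biological explanation was tested.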
